A study of Mus musculus with 8 samples.

How the data were processed

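The data were 8 Affymetrix expression arrays of mouse total RNA, 6 from primary soft tissue sarcomas and 2 from normal muscle. The deposited values were log2 expression per probe set, already processed by the authors, and per the submitters' processing notes they came from RMA, a method that corrects background, makes the arrays share 1 distribution and summarises the probes of a set. The version of RMA was not stated, and whether the 8 arrays were processed together was not given in the sources used here. The log2 scale of the deposited values was also read from their range, since all 8 columns had near-equal quantiles with medians from 5.79 to 5.90. Batch and scan date were not given in the sources used here. Because values that share 1 distribution sum to a near-constant signal, a change in the total RNA content of a tissue is not measured by them.

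Groups came from the sample titles, which give the tissue, the Braf genotype (Ca/Ca or Ca/+) and a tumour number. The Ca/Ca sarcomas carried the numbers 1, 2, 3 and 5, the Ca/+ sarcomas the numbers 1 and 2, and each genotype had 1 muscle. The labels did not say that the arrays came from separate animals, so p-values measure the spread between these samples, which may be partly technical. No array was a copy of another, with at most 32 equal values between any pair over 12393 genes.

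The table held 22690 probe sets, of which 64 were control probe sets and 22626 were not. The platform annotation listed 21084 probe sets. After controls were left out, 20380 probe sets had 1 gene symbol, 691 had several and were not named, and 1555 were not listed and stayed unnamed. Of the named probe sets, 20351 had an Entrez number in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used here for names and for the order of neighbouring genes. The gene test used 1 probe set per gene, the one with the highest mean over the 8 arrays, which gave 12393 genes, 4956 of them with more than 1 probe set. A total of 0 columns belonged to other samples.

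Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on log2 values), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and every adjusted p printed for a gene comes from that fit. Sarcoma against muscle used all 8 arrays. Ca/Ca against Ca/+ sarcoma used the 6 sarcomas alone. The interaction of tissue and genotype used 4 groups of 4, 2, 1 and 1 arrays, which left 4 residual degrees of freedom, all from the sarcomas, so each lone muscle was assumed to vary like the sarcomas. The same assumption held for a lone muscle when the other muscle was left out. The 2 muscles were also compared as values with no test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

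A total of 32 gene lists were fixed, and 623 of their 697 members were matched to a measured gene by symbol or synonym. They were tested with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. A call of a list means the preset test unless another is named. Counts per list are given over all genes tested and adjusted over the list alone. List means per array were compared by exact two-sided permutation tests, over 28 splits for 6 against 2 (smallest p 0.0357) and 15 splits for 4 against 2 (smallest p 0.0667). The groups, the tests, the lists, the rule for named genes and the alternatives, other than those named as added, were chosen before the data were examined.

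The rule for named genes began with Braf and Trp53 in every sample, and no probe set named Trp53 was analysed here. For sarcoma against muscle it took the 5 largest increases and 5 largest decreases among genes past the threshold whose 6 sarcomas all lay on 1 side of both muscles, then the 2 members that changed most in the direction of each called list, then every member of the lists for MAPK output, p53 targets, the Cdkn2 and Rb axis and microRNA processing. For the other tested comparisons it took the 5 largest increases and decreases that passed without overlap of the groups, or all that passed where fewer did, or the 3 genes of smallest p in each direction where none passed, and the 2 members with the largest absolute change of each called list. For the muscles it took the 3 largest differences in each direction. Genes outside this rule are said to have been chosen after their values were seen.

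The procedure was tested on simulated data, 5 runs over 12393 genes in which, in all, 340 genes were changed by 2-fold, 330 by 4-fold and 330 by 16-fold. For sarcoma against muscle it recovered 54.4% of 2-fold, 79.1% of 4-fold and 96.7% of 16-fold changes, with 4.73% of calls false. For Ca/Ca against Ca/+ sarcoma, again over 12393 genes, the shares were 33.8%, 80.6% and 92.4%, with 5.25% false. For the interaction over 12393 genes they were 0.294%, 33% and 76.7%, with 5.47% false. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs of each comparison, and unshifted lists were called 1 time in each. The simulated noise was drawn for each gene on its own, so these list rates do not cover lists whose genes vary together. Its spread came from the residuals of the 4 groups, to which a lone muscle adds none. The difference between the 2 muscles was thus not simulated, and recovery for sarcoma against muscle may be overstated.

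Alternatives changed 1 choice at a time: trend and robust eBayes, array weights, leaving out the dimmest 25% or 50% of genes, every probe set as its own feature, the mean of a gene's probe sets, 6 other scalings between arrays, a minimum change of 2-fold, treat against 1.5-fold, leaving out each array in turn, Braf genotype as a covariate, arrays of 1 genotype alone, the tumour number as a block, all 8 arrays for the sarcoma genotypes, and the muscle gene level as a covariate. The 6 scalings were median centring, a second quantile normalization, cyclic loess, and centring on housekeeping genes, on ribosomal protein genes or on 18 hybridization control probe sets. The fits without both the Ca/Ca muscle and Ca/Ca sarcoma 5, and without the neighbours of Tfdp1, were added after seeing the data. For arrays, precision is limited by their number.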

Results

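Total RNA was measured on 8 arrays, from 6 primary soft tissue sarcomas and from 2 muscles taken from hind limbs without a tumour. The mice carried the BrafCa allele, on both chromosomes (Ca/Ca) or on 1 (Ca/+), together with floxed p53 alleles, and tumours were started by an adenovirus that carries Cre, the recombinase that acts on floxed sites. There were 4 Ca/Ca sarcomas, 2 Ca/+ sarcomas and 1 muscle of each genotype. Braf, the targeted kinase gene, had a log2 level of 4.76 ± 0.21 (SD, n = 6) in sarcomas and 4.56 ± 0.09 (SD, n = 2) in muscles. On single arrays Braf ranged from 4.45 in Ca/+ sarcoma 2 to 5.07 in Ca/Ca sarcoma 5, with 4.50 in the Ca/Ca muscle and 4.62 in the Ca/+ muscle. The difference of 0.20 (SE 0.17) did not pass (adjusted p = 0.439), and its sign turned under housekeeping and ribosomal protein centring. Where the Braf probe set lies relative to the altered part of the allele was not given in the sources used here, so its level does not check the labels.

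Across 12393 genes, which are not independent replicates, Pearson's r was 0.968 between the 2 muscles, from 0.940 to 0.983 between sarcomas, and from 0.8595 to 0.932 between a sarcoma and a muscle. The first principal component held 56.5% of the variance and placed all 6 sarcomas (19.22 to 38.65) apart from both muscles (-65.7 and -95.1). The second held 16.8% and placed Ca/Ca sarcoma 5 (63.15) apart from the other arrays (-25.2 to 5.08).

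**Figure D1:**
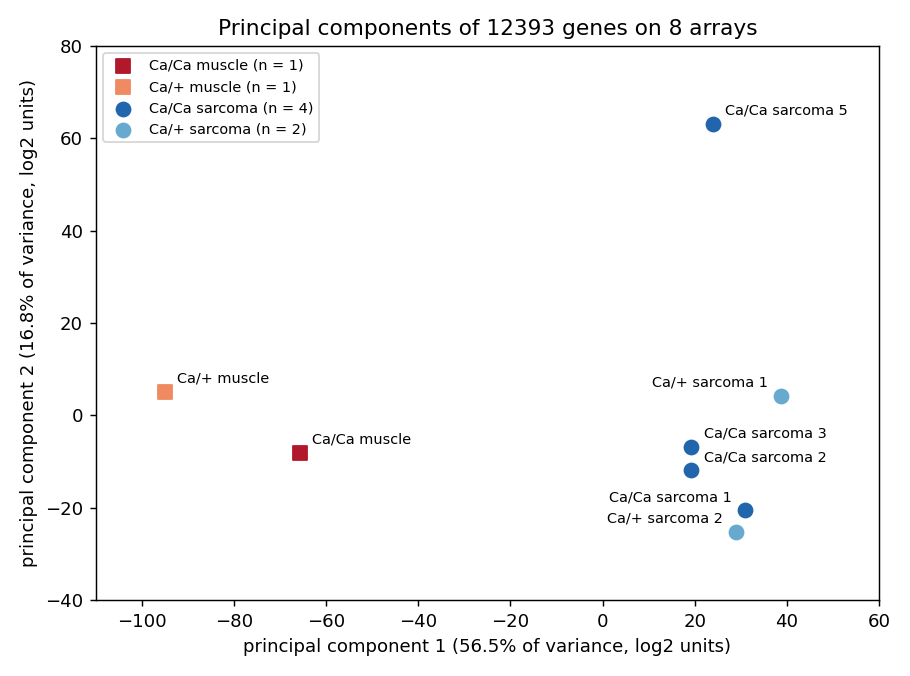
Each point is 1 array on the first and second principal components of 12393 genes, in log2 units, coloured by tissue and genotype. The 6 sarcomas lie between 19.22 and 38.65 on the first component and the muscles at -65.7 and -95.1, and Ca/Ca sarcoma 5 lies at 63.15 on the second.

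The design compares the sarcomas with normal muscle. Sarcomas held far less RNA of the contractile, mitochondrial and fat-burning genes of muscle and more RNA of cell division and ribosome assembly genes. Ckmt2, the mitochondrial creatine kinase of muscle, fell by 7.43 on the log2 scale (SE 0.45, adjusted p = 2.47e-05), from 10.43 to 3.00. Genes of the Y chromosome had levels of 2.03 to 3.72 on the 7 arrays without their RNA, so 3.00 lies at the floor of the arrays and the size of this fall is a lower bound. Hmga2, a chromatin protein of embryonic tissue, rose by 4.36 (SE 0.88, adjusted p = 0.00819), by 2.34 (0.0296) without the Ca/+ muscle and by 6.39 (0.00035) without the Ca/Ca muscle, and did not pass with Ca/Ca arrays only (2.21, 0.0993). Of 12393 genes, 3256 changed, 1626 higher and 1630 lower in sarcoma, and 754 and 1045 of these by at least 2-fold.

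Besides Ckmt2, the largest decreases were those of Phkg1, the muscle subunit of phosphorylase kinase (fell by 6.21, SE 0.20, adjusted p = 2.75e-06), Ddit4l (fell by 5.97, SE 0.40), Ldb3, a protein of the muscle Z-disc (fell by 5.96, SE 0.44), and Casq1, the calcium store protein of the sarcoplasmic reticulum (fell by 5.86, SE 0.52). Their adjusted p-values were at most 0.000181. The sarcoma mean of Phkg1 (2.76) and the muscle mean of Gap43 (3.15) also lay at the floor, so their differences are lower bounds and the ranking by size is not exact. The largest increases were those of Crabp1, a retinoic acid binding protein (4.91, SE 1.17, adjusted p = 0.0163), the neurofilament gene Nefl (4.65, SE 1.38, adjusted p = 0.0388), Hmga2, Gap43, a growth cone protein (4.30, SE 1.03, adjusted p = 0.0168), and Ptgs2, an enzyme of prostaglandin synthesis (4.27, SE 0.94, adjusted p = 0.0118). All of these genes lay on 1 side of both muscles in 6 of 6 sarcomas. Without the Ca/+ muscle the calls of Crabp1 (2.20, adjusted p = 0.0734), Nefl (1.69, 0.368), Gap43 (0.148) and Ptgs2 (0.143) were lost, and that of Gap43 also without the Ca/Ca muscle (0.0585). Nefl lost its call without any of 5 arrays, at adjusted p from 0.0537 to 0.368: the Ca/+ muscle, Ca/Ca sarcomas 5 and 3, and both Ca/+ sarcomas. Without the Ca/Ca muscle Crabp1 rose by 7.61 and Nefl by at least 7.61, as the Ca/+ muscle level of Nefl lies at the floor. The Ca/Ca muscle held more of these genes than the Ca/+ muscle, with Crabp1 at 9.78 against 4.36, Nefl at 9.05 against 3.13 and Hmga2 at 8.57 against 4.53.

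Genes of the muscle fibre fell. Of 37 contractile genes, 36 fell and 1 did not pass (36 fell adjusted over the list alone), with a median change of -4.37 (camera adjusted p = 3.69e-23), and adjusted p = 0.266 with an estimated correlation. The list mean was 7.20 ± 0.57 (SD, n = 6) in sarcomas and 11.19 ± 0.11 (SD, n = 2) in muscles. Of 21 myogenic regulators and satellite cell genes, 13 fell and 8 did not pass (14 fell and 1 rose adjusted over the list alone), with a median of -0.73 (camera adjusted p = 2.59e-06), and adjusted p = 0.33 with an estimated correlation. Actc1, an actin of heart and developing muscle, fell by 5.51 and Myf6, a myogenic transcription factor, fell by 3.53. All 34 genes of oxidative phosphorylation and the citrate cycle fell, also adjusted over the list alone, with a median of -1.19 (camera adjusted p = 5.22e-21), and adjusted p = 0.266 with an estimated correlation. Cox8b and Cox7a1, the muscle forms of cytochrome oxidase subunits, fell by 5.78 and by 5.42. Of 20 fatty acid use genes, 19 fell and 1 did not pass (20 fell adjusted over the list alone), median -1.79 (camera adjusted p = 1.03e-14), and adjusted p = 0.266 with an estimated correlation. Fabp3, a fatty acid carrier, fell by 5.28 and Cd36, a fatty acid transporter, by 4.29. Of 19 glycolysis and glycogen genes, 11 fell, 2 rose and 6 did not pass (11 and 3 adjusted over the list alone), median -1.25 (camera adjusted p = 7.25e-05), and adjusted p = 0.385 with an estimated correlation. Pygm, the muscle glycogen phosphorylase, fell by 5.51 and Pgam2, the muscle phosphoglycerate mutase, fell by 5.41, while the widely expressed mutase gene Pgam1 (1.28) and the glucose transporter gene Slc2a1 (1.68) rose. These lists kept their sign and call under all 6 scalings and without any 1 array, and the myogenic call was lost without the dimmest 50% of genes (adjusted p = 0.0929).

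Markers of blood vessels and fat fell as well. Of 19 endothelial genes, 13 fell and 6 did not pass (15 fell adjusted over the list alone), median -1.29 (camera adjusted p = 5.24e-07), and adjusted p = 0.385 with an estimated correlation. Vwf, a clotting protein made by endothelium, fell by 2.87 and the angiopoietin receptor gene Tek fell by 2.41. Of 14 adipocyte genes, 12 fell and 2 did not pass (13 fell adjusted over the list alone), median -3.54 (camera adjusted p = 8.75e-08), and adjusted p = 0.385 with an estimated correlation. Cidec, a lipid droplet protein, fell by 5.45 and the adipokine gene Adipoq fell by 5.39. The call of Adipoq was lost without the Ca/+ muscle (adjusted p = 0.125), which had the higher adipocyte list mean of the 2 muscles (10.68 against 8.60).

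Cell division and ribosome assembly genes rose. Of 41 cell cycle and DNA replication genes, 32 rose, 0 fell and 9 did not pass (39 rose adjusted over the list alone), median 1.83 (camera adjusted p = 1.24e-11), and adjusted p = 0.435 with an estimated correlation. Cdk1, the mitotic kinase, rose by 2.88 and Birc5, a mitotic and survival protein, rose by 2.79, and both calls were lost without the Ca/+ muscle (adjusted p = 0.0648 and 0.199). Of 19 ribosome biogenesis genes, 13 rose and 6 did not pass (15 rose adjusted over the list alone), median 0.79 (camera adjusted p = 4.97e-07), and adjusted p = 0.385 with an estimated correlation. Nop58 (1.87) and Nhp2 (1.34), proteins of small nucleolar particles, rose. Of 19 protein folding and secretion genes, 12 rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone), median 0.77 (camera adjusted p = 0.00065), and adjusted p = 0.397 with an estimated correlation. Sec61a1, the pore of the secretory pathway, rose by 1.47 and Herpud1 fell by 1.05. Kdelr3, a retrieval receptor, rose by 1.67 and lost its call without any of 5 arrays (the Ca/+ muscle, Ca/Ca sarcomas 1, 2 and 3, and Ca/+ sarcoma 2), at adjusted p from 0.0567 to 0.362 and a difference of 0.95 without that muscle. Without it the folding list median was 0.49 and passed (0.00303). Of 18 ribosomal protein genes, 4 rose and 14 did not pass, the same counts adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.0007, and adjusted p = 0.435 with an estimated correlation) that turned to -0.03 and -0.05 under housekeeping and ribosomal protein centring, and the call was lost under cyclic loess (adjusted p = 0.274) and with Ca/+ arrays only (0.152). Rpl14 (0.97), Rps3 (0.56), Rpl19 (0.55) and Rpl8 (0.45) rose, and Rpl14 and Rps3 lost their calls without the Ca/+ muscle (adjusted p = 0.0809 and 0.0578) and without the Ca/Ca muscle (0.078 and 0.133).

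Among stromal and immune groups, 22 matrix protease and inhibitor genes had 5 that rose, 1 that fell and 16 that did not pass (8 and 1 adjusted over the list alone), median 1.25 (camera adjusted p = 0.0103), and adjusted p = 0.435 with an estimated correlation. Timp1, a metalloprotease inhibitor, rose by 3.53, Plau, the urokinase gene, by 2.26, its receptor gene Plaur by 1.75, and the lysosomal protease genes Ctsl and Lgmn by 1.30 each, while Adamts5 fell by 2.06. Of 28 macrophage and monocyte genes, 2 rose and 26 did not pass (0 adjusted over the list alone, by limma), median 0.93 (camera adjusted p = 0.00564), and adjusted p = 0.603 with an estimated correlation. The 2 were Ms4a7 (2.05) and the lysosomal marker Cd68 (0.98). Of 29 cytokine and chemokine genes, 3 rose and 26 did not pass, also adjusted over the list alone, median 0.72 (camera adjusted p = 0.0103), and adjusted p = 0.462 with an estimated correlation. The 3 were the growth factor genes Ereg (4.21, a lower bound as its Ca/+ muscle level lies at the floor) and Hbegf (2.56) and the chemokine gene Ccl12 (2.59). Without the Ca/+ muscle the calls of all 3 lists were lost, at medians of 0.48 for proteases (adjusted p = 0.19), 0.23 for macrophages (0.529) and 0.40 for cytokines (0.177), and so were those of Timp1 (1.11, 0.172), Plau (1.27, 0.138), Ms4a7 (1.03, 0.401), Cd68 (0.41, 0.443), Ereg (2.19, 0.149) and Ccl12 (0.225). Without the Ca/Ca muscle the macrophage median was 1.59, and Timp1 rose by 5.95 and Cd68 by 1.54. The 3 list calls were also lost without the dimmest 50% of genes (adjusted p = 0.139, 0.0929 and 0.284, in the same order) and with Ca/Ca arrays only (0.11, 0.469 and 0.104). The cytokine call was lost also without the dimmest 25% (0.0589). Over 23 alternatives the call was kept in 20 for proteases, 20 for macrophages and 19 for cytokines. Timp1 lost its call without any of 5 arrays (that muscle, Ca/Ca sarcomas 1, 2 and 3, and Ca/+ sarcoma 2), at adjusted p from 0.0574 to 0.172. Ms4a7 and Cd68 each lost it without any of 6 arrays, at adjusted p from 0.0606 to 0.401 and from 0.0592 to 0.443. For both, these were the Ca/+ muscle, Ca/Ca sarcomas 1, 2 and 3, and Ca/+ sarcoma 2, with Ca/+ sarcoma 1 for Ms4a7 and Ca/Ca sarcoma 5 for Cd68. The macrophage list mean was 9.47 in the Ca/Ca muscle, 7.89 in the Ca/+ muscle and 9.60 ± 0.61 (SD, n = 6) in sarcomas.

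Collagen and matrix genes did not pass as a list. Of 27, 3 rose and 24 did not pass (0 adjusted over the list alone), median 0.24 (camera adjusted p = 0.179), negative under cyclic loess, housekeeping and ribosomal protein centring. Of 23 fibroblast and mesenchymal genes, 7 rose, 1 fell and 15 did not pass (9 and 2 adjusted over the list alone), median 0.53 (camera adjusted p = 0.0693). Without the Ca/Ca muscle the list medians were 0.95 and 0.73, and the fibroblast list passed without Ca/Ca sarcoma 3 (0.57, adjusted p = 0.032). The 3 collagen list genes that rose were Vcan (1.90), P4ha1 (1.21) and Tgfbi (1.20), and the fibroblast gene that fell was Dpt (by 3.04). The collagen list mean was 10.13 in the Ca/Ca muscle and 8.86 in the Ca/+ muscle. Of 26 antigen presentation and interferon genes 0 passed in limma, also adjusted over the list alone, median 0.39 (camera adjusted p = 0.38), and without Ca/Ca sarcoma 5 the list passed (0.81, adjusted p = 0.0206). Of 23 alternatives, 18 left the collagen list, 15 the fibroblast list and 18 the antigen presentation list without a call. All 3 passed under housekeeping centring (adjusted p = 0.0174, 0.00188 and 0.0174), under ribosomal protein centring (0.00913, 0.00222 and 0.00913) and with Ca/+ arrays only (3.32e-06, 0.00122 and 0.00388). The fibroblast list passed also with array weights (0.0462) and the mean of probe sets (0.0484). None of 15 neutrophil and mast cell genes (median 0.015, adjusted p = 0.993) and none of 21 lymphocyte genes (median -0.19, adjusted p = 0.693) passed, and these medians turned sign under 4 and 1 of the scalings. Over all genes limma called 3256 at the same threshold, with 4696 at an unadjusted p under 0.05.

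Members of the lists named here, other than Nefl, Hmga2 and Fos, were chosen after their values were seen, as were Hbegf, Plaur, Ctsl, Lgmn, Adamts5, Pgam1, Slc2a1, Herpud1, Rpl19, Rpl8, Vcan, P4ha1, Tgfbi and Dpt above. Nerve and Schwann cell genes had 3 that rose and 5 that fell of 13 (3 and 6 adjusted over the list alone; Nefl 4.65, Nefm 3.66 and Ncam1 2.84 against Ncmap -2.39, S100b -1.89, Mal -1.25, Scn7a -1.06 and Erbb3 -0.88), with a median of -0.54, a mean of 0.12 and a camera test that pointed down (adjusted p = 0.0986), and the list passed without the Ca/+ muscle (-0.54, adjusted p = 0.00241). The nerve median turned to 2.84 without the dimmest 50% of genes (adjusted p = 0.654), and the list passed with the mean of probe sets (0.0349), genotype as a covariate (0.043) and Ca/Ca arrays only (0.00284). Erythroid genes had 2 of 5 that fell (Alas2 -2.18, Slc4a1 -1.28, median -0.15, adjusted p = 0.124), skin and epithelial genes 1 of 15 that fell (Trp63 -0.83, median -0.08, mean 0.02, adjusted p = 0.318), and bone and cartilage genes 1 that rose and 4 that fell of 12 (Sox9 1.501 against Cnmd, at the floor in both tissues, Chad -1.41, Comp -1.19 and Alpl -0.87, median -0.16, adjusted p = 0.11, and -0.27, adjusted p = 0.0117 without the Ca/+ muscle), and all 3 medians turned sign under hybridization control centring. Hypoxia genes had 2 that rose and 3 that fell of 15 (Slc2a1 1.68 and P4ha1 1.21 against Pfkfb3 -3.03, Bnip3 -1.80 and Ldha -1.15, and 4 and 3 adjusted over the list alone), with a median of 0.12 that turned under 3 scalings, a mean of -0.14 and adjusted p = 0.873. Acute stress genes had 3 of 16 that fell (Nr4a1 -2.68, Fos -1.74, Klf4 -0.74, median -0.37, adjusted p = 0.142, and -0.62, adjusted p = 0.0348 without Ca/Ca sarcoma 1). Imprinted and embryonic growth genes had 1 that rose (Hmga2) and 2 that fell (Peg3 -2.87, Gpc3 -2.03) of 13, with a median of 0.06 that turned under 3 scalings and a camera test that pointed down (adjusted p = 0.8293). Housekeeping genes had 2 of 12 that rose (Vps29 0.90, Tbp 0.59, median 0.21, which turned under 3 scalings, adjusted p = 0.128) and receptor tyrosine kinases 2 of 13 (Axl 1.45, Mertk 1.30, median 0.41, adjusted p = 0.124). The kinases passed under housekeeping (adjusted p = 0.031) and ribosomal protein centring (0.0295) and with Ca/+ arrays only (0.0188), acute stress with Ca/+ arrays only (0.0119) and bone with Ca/Ca arrays only (0.0424). The sarcoma means of Scn7a, Slc4a1, Trp63 and Chad and the Ca/+ muscle levels of Nefl and Nefm lay at the floor, so their differences are lower bounds. For the erythroid, skin, bone, stress, imprinted, housekeeping and kinase lists, the counts were the same adjusted over the list alone.

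Genes of the MAPK pathway output, which report signalling downstream of Braf, rose as a list. Of 19, 9 rose, 1 fell and 9 did not pass (14 and 1 adjusted over the list alone), median 1.24 (camera adjusted p = 0.000791), and adjusted p = 0.435 with an estimated correlation. The transcription factor gene Fosl1 (2.79), the cyclin gene Ccnd1 (2.65), Il1rap (2.15), Etv4 (1.97), the feedback inhibitor genes Spred1 (1.69), Dusp6 (1.65) and Spry4 (0.75), Phlda1 (1.31) and Myc (1.24) rose, and the immediate early gene Fos fell by 1.74. Differences that did not pass were 1.48 for Ier3, 1.46 for Epha2, 1.19 for Spred2 (whose other probe set had the opposite sign), 1.01 for Etv5, 0.83 for Spry2, 0.72 for Elk3, -0.27 for Epha4, -0.36 for Spry1 and -0.41 for Egr1. Without the Ca/Ca muscle Ccnd1 rose by 4.01 and Phlda1 by 2.16. Without the Ca/+ muscle the calls of Ccnd1 (1.29, adjusted p = 0.107), Il1rap (1.35, 0.0964), Dusp6 (0.998, 0.159), Spry4 (0.177), Phlda1 (0.47, 0.436), Myc (0.213) and Fos (0.186) were lost. Phlda1 lost its call without any array other than the Ca/Ca muscle and Ca/Ca sarcoma 3, at adjusted p from 0.0604 to 0.436. Without Ca/Ca sarcoma 3, Elk3 (adjusted p = 0.0111), Etv5 (0.0137), Spred2 (0.00571) and Spry2 (0.0393) passed, and Epha2 passed without Ca/Ca sarcoma 5 or Ca/+ sarcoma 2 (adjusted p from 0.0175 to 0.0483).

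Targets of p53 did not pass as a list (median -0.0048, which turned under hybridization control centring, mean -0.48, camera adjusted p = 0.157). The directional test of fry did pass for them (adjusted p = 0.000243). Of 20, 6 fell, 0 rose and 14 did not pass, the same counts adjusted over the list alone. Ddit4l fell by 5.97, the cyclin gene Ccng1 by 2.21, Phlda3 by 1.37, the death receptor gene Fas by 1.35, Btg2 by 1.34 and Ei24 by 0.71. The p21 gene Cdkn1a (0.45, SE 0.30, adjusted p = 0.317), Mdm2 (0.23, SE 0.19, adjusted p = 0.415, negative under housekeeping and ribosomal protein centring) and Pmaip1 (1.57, SE 0.63, adjusted p = 0.102) did not pass, nor did Gadd45a (0.68), Plk2 (0.38), Tnfrsf10b (0.23), Bbc3 (0.15), Zmat3 (0.11), Polk (0.056), Trp53inp1 (0.034), Perp (-0.043), Sesn1 (-0.080), Sesn2 (-0.14) and Aen (-0.33). The other probe set of Trp53inp1 and both others of Aen had the opposite sign. Without the Ca/+ muscle the calls of Phlda3 (-0.82, adjusted p = 0.246), Fas (0.219) and Btg2 (0.223) were lost, and without the Ca/Ca muscle that of Ei24 (0.0708). Pmaip1 passed without Ca/+ sarcoma 1 (adjusted p = 0.0282) and Aen without Ca/+ sarcoma 2 (0.0486).

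In the Cdkn2 and Rb axis 4 of 10 genes rose, 2 fell and 4 did not pass, the same counts adjusted over the list alone, and the list did not pass (median 0.88, camera adjusted p = 0.203). Cdkn2a, which encodes inhibitors of the cell cycle, rose by 4.39 (SE 1.16, adjusted p = 0.0246) to 10.996 ± 1.13 (SD, n = 6), and its neighbour Cdkn2b rose by 3.39 (SE 0.65, adjusted p = 0.00643). The kinase genes Cdk4 (1.68, adjusted p = 0.00167) and Cdk6 (0.81, adjusted p = 0.0484, a lower bound as its muscle mean of 3.46 lies at the floor) rose, and the retinoblastoma gene Rb1 (fell by 0.91, adjusted p = 0.0221) and the inhibitor gene Cdkn1b (fell by 0.85, adjusted p = 0.0343) fell. Cdkn1c (1.11), Rbl1 (0.96), E2f3 (0.095) and Cdkn2c (-0.45) did not pass. Without the Ca/+ muscle the calls of Cdkn2a (2.11, adjusted p = 0.254), Cdkn2b (2.12, 0.0592), Rb1 (0.197), Cdkn1b (0.212) and Cdk6 (0.205) were lost, and without the Ca/Ca muscle those of Rb1 (0.0557), Cdkn1b (0.109) and Cdk6 (0.185). Cdk6 lost its call also without Ca/Ca sarcoma 1 or 5 or either Ca/+ sarcoma (adjusted p from 0.0672 upward), and Cdkn1b without Ca/Ca sarcoma 2 or 3 or Ca/+ sarcoma 2 (from 0.0546 upward). Cdkn1c passed without Ca/Ca sarcoma 2 (adjusted p = 0.0373) and Rbl1 without Ca/Ca sarcoma 5 (0.0191). The list passed under housekeeping centring (adjusted p = 0.0447). Without the Ca/Ca muscle Cdkn2a rose by 6.68. Cdkn2a stood at 8.88 in the Ca/Ca muscle and 4.32 in the Ca/+ muscle, and at 8.78 in Ca/+ sarcoma 2, below the Ca/Ca muscle.

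Of 8 microRNA processing genes 3 rose and 5 did not pass, the same counts adjusted over the list alone, and the list did not pass (median 0.32, which turned under housekeeping and ribosomal protein centring, camera adjusted p = 0.202). Ago2, the slicer of small RNA complexes, rose by 0.89 (adjusted p = 0.0264), and Tarbp2 (0.59, adjusted p = 0.0078) and Prkra (0.59, adjusted p = 0.0143), partners of Dicer1, rose. Dicer1 (-0.11), Dgcr8 (-0.34), Xpo5 (0.46), Ddx5 (-0.25) and Ddx17 (0.18, with 1 of 2 other probe sets of opposite sign) did not pass. Without the Ca/+ muscle all 3 calls were lost (adjusted p = 0.152 for Ago2, 0.0693 for Tarbp2 and 0.118 for Prkra), and without the Ca/Ca muscle those of Ago2 (0.118) and Prkra (0.0653). Ago2 lost its call also without Ca/Ca sarcoma 2 (0.0507).

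**Figure D2:**
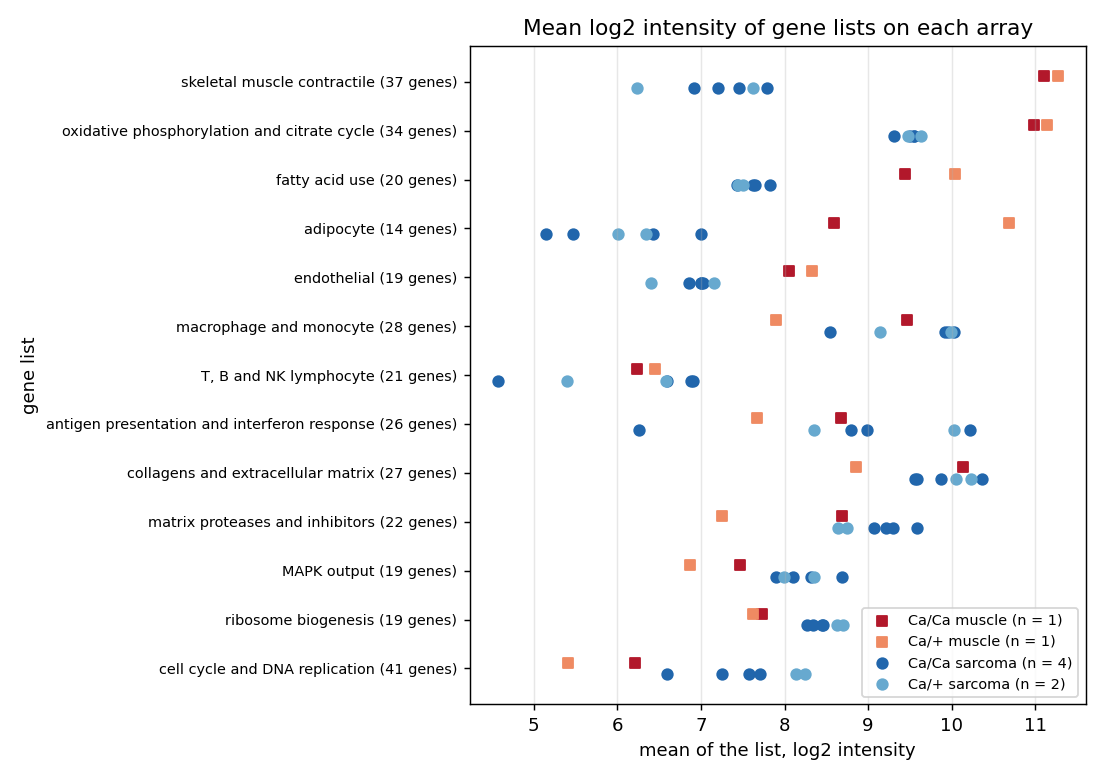
Points give the mean log2 intensity of the genes of a list on each array, with the number of genes in brackets. Contractile genes lie at 11.1 and 11.3 in the muscles and at most 7.78 in the sarcomas, and the macrophage list stands at 9.47 in the Ca/Ca muscle, 7.89 in the Ca/+ muscle and 9.60 on average in sarcomas.

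**Figure D3:**
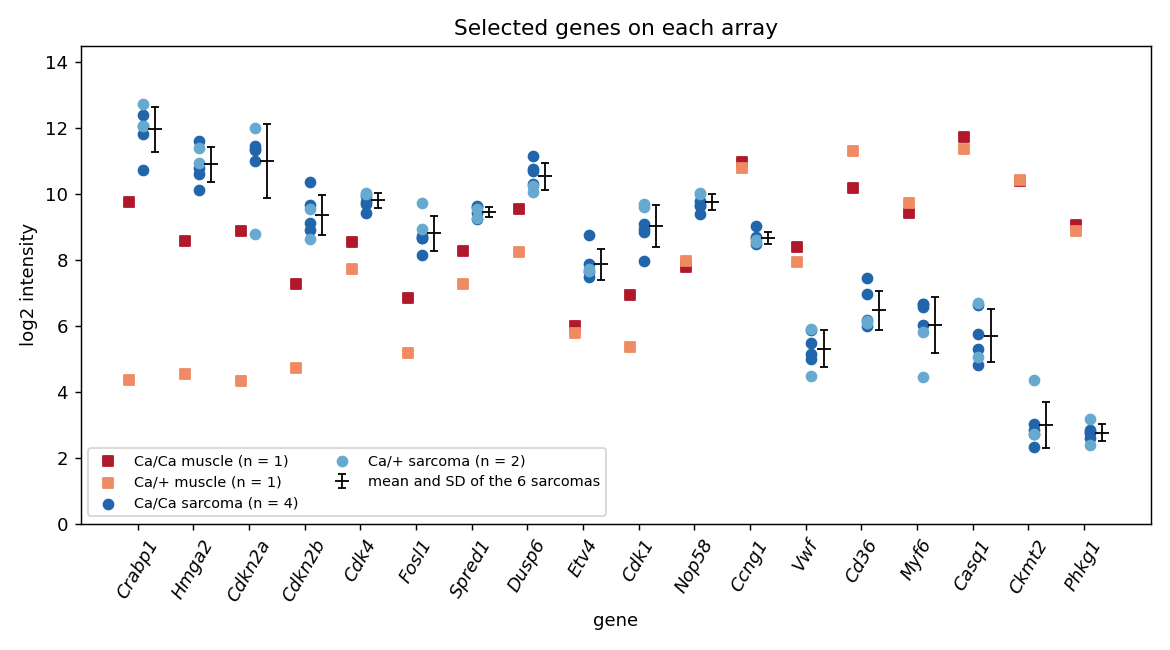
Points give the log2 intensity of named genes on each array, and bars the mean and SD of the 6 sarcomas. Ckmt2 fell by 7.43, a lower bound as its sarcoma mean of 3.00 lies at the floor, Hmga2 rose by 4.36, and for Crabp1 and Cdkn2a the Ca/Ca muscle (9.78 and 8.88) lies between the Ca/+ muscle (4.36 and 4.32) and the sarcoma mean (11.97 and 10.996).

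At the threshold, 620 genes would have an unadjusted p under 0.05 by chance, and 4696 did. All 6 sarcomas lay above both muscles for 2473 genes and below both for 2350, where chance gives 7.14% of genes in both directions together, and 3228 of the called genes separated in this way. Of the called genes named above, Cdkn2a, Kdelr3, Ms4a7, Peg3 and Sox9 did not, each with 1 sarcoma beyond the Ca/Ca muscle. The number called rested on the Ca/+ muscle, without which 1195 genes passed (372 higher, 823 lower), and fell to 1040 higher and 1288 lower, 2328 in all, without the Ca/Ca muscle. Of 93 named genes 60 passed, and 34 of these 60 lost their call without the Ca/+ muscle. The median took the other sign in at least 1 alternative for 13 of 17 lists without a call and for 1 of 15 with a call. Without both the Ca/Ca muscle and Ca/Ca sarcoma 5, a fit added after seeing the data, 2746 genes passed (1321 higher, 1425 lower). The main split had 49.9% of calls higher, and scaling moved it to 35.5% under cyclic loess, 18.9% under housekeeping, 13.5% under ribosomal protein and 63.2% under hybridization control centring. The median change of all genes was 0.026, and these centrings moved it to -0.33 (housekeeping), -0.35 (ribosomal protein) and 0.26 (hybridization controls), so directions of small changes hold relative to the scaling used. No list call held with an estimated correlation in any of the 3 tested comparisons. Exact permutation tests of list means gave 0.0357, the smallest p possible, for lists such as contractile, cell cycle and MAPK output, adjusted to 0.0672. The directional test of fry gave adjusted p-values of 0.000278 for contractile genes, 0.021 for cell cycle, 0.0166 for MAPK output, 0.245 for macrophages and 0.127 for cytokines. Among lists without a camera call it passed for p53 targets (0.000243), erythroid genes (0.0096), the Cdkn2 and Rb axis (0.0115) and microRNA processing (0.0228). It passed also for housekeeping genes (0.0319), bone (0.0349), nerve (0.0446) and the kinases (0.0446). Its mixed test, which asks for change in either direction, gave 3.99e-06 for p53 targets.

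Ca/Ca and Ca/+ sarcomas were compared to see whether gene levels went with the number of BrafCa alleles. No single gene separated the genotypes past the threshold. Cell cycle genes were called lower as a list in the 4 Ca/Ca sarcomas by the preset camera test, and by no other list test. limma called 0 of 12393 genes, with a smallest adjusted p of 0.196 and 971 genes at an unadjusted p under 0.05, where chance gives 620. Cell cycle genes had a list mean of 7.28 ± 0.50 (SD, n = 4) in Ca/Ca and 8.19 ± 0.07 (SD, n = 2) in Ca/+ sarcomas. Their median difference was -0.84 (camera adjusted p = 4.92e-20), 8 of 41 were lower adjusted over the list alone (Prc1, Aurkb, Ttk, Tpx2, Kif20a, Aurka, Ccne1 and E2f1, named after their values were seen). The call was lost with an estimated correlation (adjusted p = 0.57). For this list fry did not pass (adjusted p = 0.324 directional and 0.24 mixed). The exact permutation test of its list mean gave p = 0.133, adjusted to 0.64. The preset test compares the genes of a list with other genes and does not show that the genotypes differ.

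The genes of smallest p that were higher in Ca/Ca sarcomas, none past the threshold, were Gda, a guanine deaminase (1.68, SE 0.22, adjusted p = 0.374), the acute phase gene Saa3 (2.42, SE 0.39, adjusted p = 0.535) and the kinase gene Prkg2 (2.49, SE 0.41, adjusted p = 0.535). Those lower were the interferon-induced gene Ifi44l (-3.59, SE 0.33, adjusted p = 0.196), Tfdp1, the partner of E2F factors (-2.49, SE 0.24, adjusted p = 0.196), and Tro (-1.32, SE 0.14, adjusted p = 0.262). Tfdp1 stood at 8.40 ± 0.08 (SD, n = 4) in Ca/Ca and 10.89 ± 0.58 (SD, n = 2) in Ca/+ sarcomas, with 11.30 in Ca/+ sarcoma 1 and 10.48 in Ca/+ sarcoma 2. Ifi44l passed in 2 alternatives, without Ca/+ sarcoma 1 (-4.22, adjusted p = 0.0146) and under hybridization control centring (-3.79, adjusted p = 0.00319), and its adjusted p ranged from 0.00319 to 0.738 over the alternatives. Its level in the 4 Ca/Ca sarcomas (2.80 to 2.89) lay at the floor, so these differences are lower bounds. Tools and settings other than these 2 also gave 0 genes, and treat against 1.5-fold left 122 at an unadjusted p under 0.05.

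**Figure D4:**
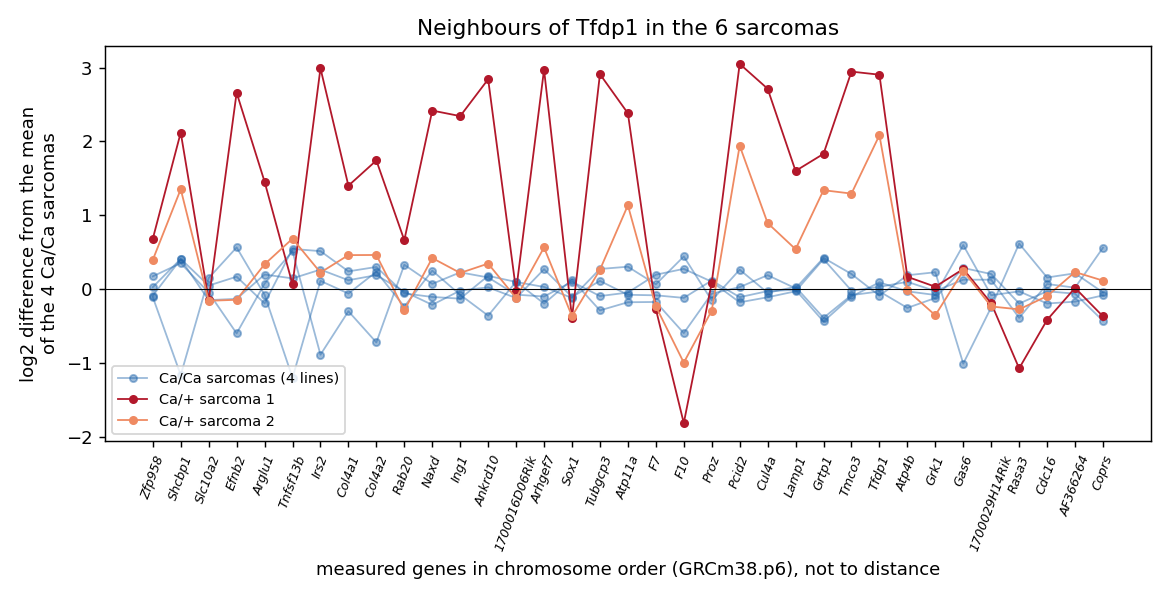
Points give measured genes in their chromosome order (assembly GRCm38.p6, not to distance) as the difference of each of the 6 sarcomas from the mean of the 4 Ca/Ca sarcomas. Over all 17 genes measured from Naxd to Tfdp1 the median was 2.38 in Ca/+ sarcoma 1 and 0.42 in Ca/+ sarcoma 2.

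Cell cycle and ribosome biogenesis genes kept their calls without any 1 array. Among cell cycle genes the mitotic genes Aurkb (-1.54) and Prc1 (-1.42) differed most and did not pass. The lowest cell cycle list mean, 6.60, was that of Ca/Ca sarcoma 5. Ribosome biogenesis genes had a median of -0.29 (camera adjusted p = 6.58e-05, and adjusted p = 0.57 with an estimated correlation) and a median from -0.493 to -0.0941 over the alternatives, with Utp20 at -0.78 and Fbl at -0.41. Called higher in Ca/Ca sarcomas were skeletal muscle contractile genes (median 0.48, adjusted p = 0.0141, and adjusted p = 0.778 with an estimated correlation; Mb 1.56, Tnni2 1.24), myogenic regulators (0.15, adjusted p = 0.0143, and adjusted p = 0.614 with an estimated correlation; Myf6 1.35, Myl4 1.09), matrix proteases (0.24, adjusted p = 0.025, and adjusted p = 0.57 with an estimated correlation; Mmp13 3.33, Mmp9 2.56), cytokines (0.38, adjusted p = 0.025, and adjusted p = 0.778 with an estimated correlation; Cxcl14 2.27, Ccl6 2.02), skin and epithelial genes (0.21, adjusted p = 0.0444, and adjusted p = 0.614 with an estimated correlation; Krt18 2.90, Dsp 1.61) and ribosomal protein genes (0.086, adjusted p = 0.0444, and adjusted p = 0.778 with an estimated correlation; Rpl37 0.59, Rpl27a 0.43). Imprinted and embryonic growth genes were called lower (-0.39, adjusted p = 0.0444, and adjusted p = 0.57 with an estimated correlation), with Ndn at -1.68 and Plagl1 at -1.45. None of these genes passed, 4 of 22 proteases (Mmp13, Mmp19, Adamts5 and Timp1, named after their values were seen) were higher adjusted over the list alone, and the other 6 lists in this group had 0. The mean of Dsp in Ca/+ sarcomas (3.31) lay at the floor, so its difference is a lower bound. The opposite sign was found for 1 of 2 other probe sets of Tnni2 and 1 of 7 of Ndn. Over the alternatives Tnni2 ran from 0.0127 to 2.47, Mb from 0.839 to 2.24 and Myf6 from 0.657 to 2.05. Krt18 ran from 1.32 to 4.47, Cxcl14 from 1.24 to 3.29 and Ccl6 from 1.21 to 2.82. Mmp13 lay in a run of neighbouring genes that were high in Ca/Ca sarcoma 1, where it stood at 9.87, and it stood at 8.62 in Ca/Ca sarcoma 3. The protease list genes Mmp12 and Mmp3 lay in the same run and Mmp10 next to it. Mmp12 stood at 7.37 and 7.38 and Mmp10 at 10.94 and 11.79 in Ca/Ca sarcomas 1 and 3. These list members are therefore not independent of each other. Under hybridization control centring the medians of myogenic regulators (-0.047) and ribosomal protein genes (-0.12) turned.

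Of 21 alternatives, all kept the calls of cell cycle and ribosome biogenesis. Of the same 21, 19 kept that of myogenic regulators, 18 of proteases, 17 of contractile genes, 16 of cytokines and 13 each of ribosomal protein and imprinted genes. For skin genes 9 of 20 kept the call. The contractile call was lost without Ca/Ca sarcoma 2 (median 0.34, adjusted p = 0.134) and its median turned to -0.31 without Ca/+ sarcoma 1 (0.0604). The myogenic call was lost without Ca/Ca sarcoma 2 (adjusted p = 0.0691), and the protease call without Ca/Ca sarcoma 1 (0.0835) or Ca/+ sarcoma 2 (0.193). The cytokine call was lost without Ca/Ca sarcoma 3 (0.0619), Ca/Ca sarcoma 1 (0.16) or Ca/+ sarcoma 1 (0.367). The skin call was lost without Ca/Ca sarcoma 5 (0.0534), Ca/Ca sarcoma 3 (0.088) or Ca/+ sarcoma 2 (0.25). The ribosomal protein call was lost without Ca/Ca sarcoma 3 (0.193), Ca/Ca sarcoma 2 (0.0698) or Ca/+ sarcoma 1 (0.263). The imprinted call was lost without Ca/Ca sarcoma 3 (0.0619), Ca/Ca sarcoma 2 (0.0534), Ca/+ sarcoma 1 (0.0534) or Ca/+ sarcoma 2 (0.115). Without Ca/Ca sarcoma 5 the medians moved to 0.0974 for myogenic regulators, 0.473 for proteases and -0.166 for imprinted genes, and without Ca/Ca sarcoma 1 to 0.236 for myogenic and -0.642 for imprinted genes. Without Ca/Ca sarcoma 3 they moved to 0.153 for cytokines, 0.0305 for ribosomal protein, -0.185 for ribosome biogenesis and -0.21 for imprinted genes. Without Ca/+ sarcoma 1 they moved to 0.499 for proteases, 0.152 for cytokines, 0.383 for skin, 0.0426 for ribosomal protein and -0.64 for imprinted genes. Without Ca/+ sarcoma 2 they moved to 1.09 for contractile genes, 0.628 for cytokines, 0.149 for ribosomal protein, -0.192 for ribosome biogenesis and -0.232 for imprinted genes. In other settings the skin call was lost with array weights (adjusted p = 0.0725), without the dimmest 25% of genes (0.146), with the mean of probe sets (0.0805), and with tumour numbers as a block (0.263). It was also lost under median centring (0.058), a second quantile normalization (0.146), cyclic loess (0.15) and housekeeping centring (0.168). The ribosomal protein call was lost with the mean of probe sets (0.0656), a second quantile normalization (0.236), hybridization control centring (0.216), the block (0.202) and the muscle gene level as a covariate (0.166). The imprinted call was lost without the dimmest 25% (0.207) or 50% (0.236) of genes, with the mean of probe sets (0.0805) and with the block (0.0773). Housekeeping centring removed the calls of contractile genes (0.316), proteases (0.254) and cytokines (0.505), and median centring that of cytokines (0.0519). The muscle gene level as a covariate removed that of contractile genes (0.652), and leaving out the dimmest 50% that of myogenic regulators (0.0879). Exact permutation tests of list means gave at best 0.0667, the smallest p possible, as for proteases and ribosome biogenesis.

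The other lists did not pass between the genotypes. Their medians and camera adjusted p were -0.12 and 0.0914 for oxidative phosphorylation, 0.046 and 0.242 for fatty acid use, -0.06 and 0.788 for glycolysis, -0.26 and 0.0954 for collagens, -0.11 and 0.29 for fibroblasts, -0.12 and 0.84 for macrophages, 0.06 and 0.712 for neutrophils and mast cells, and 0.29 and 0.331 for lymphocytes. They were -0.48 and 0.2 for antigen presentation, 0.18 and 0.131 for endothelium, 0.12 and 0.712 for adipocytes, 0.054 and 0.786 for nerve, 0.16 and 0.0954 for erythroid genes, and 0.16 and 0.0635 for bone and cartilage. They were 0.056 and 0.836 for MAPK output, 0.11 and 0.242 for p53 targets, -0.18 and 0.242 for the Cdkn2 and Rb axis, 0.0067 and 0.696 for microRNA processing, -0.18 and 0.306 for hypoxia, -0.037 and 0.877 for protein folding, 0.28 and 0.0514 for acute stress, -0.15 and 0.0954 for housekeeping genes and 0.019 and 0.29 for receptor tyrosine kinases. The mean had the other sign for glycolysis, macrophages, neutrophils, adipocytes, nerve, microRNA processing, protein folding and the kinases. The median took the other sign in at least 1 alternative for 22 of these 23 lists and for 4 of the 9 called. Acute stress stayed without a call in only 8 of 21 alternatives. It passed with array weights (adjusted p = 0.0444), without the dimmest 25% (0.0142) or 50% (0.00214) of genes, under a second quantile normalization (0.0184), cyclic loess (0.0237), ribosomal protein (0.029) and hybridization control centring (0.00514), with the block (0.00261) and with the muscle gene level (0.0259). The block compared only sarcomas 1 and 2 of each genotype, with 1 residual degree of freedom. With it lymphocytes (0.835, adjusted p = 9.34e-08), macrophages (0.295, 0.000773) and antigen presentation (0.481, 0.0052) passed. So did oxidative phosphorylation (-0.187, 0.00786), endothelium (0.325, 0.0325) and housekeeping genes (-0.147, 0.0412). With array weights lymphocytes and bone (both 0.0386) and oxidative phosphorylation and erythroid genes (both 0.0399) passed, and with the muscle gene level oxidative phosphorylation (0.0286) and antigen presentation (0.0373). Under housekeeping centring collagens (0.00215), fibroblasts (0.0388), antigen presentation (0.000755) and bone (0.0457) passed, all but bone below the median of all genes. Under hybridization control centring lymphocytes (0.0146), endothelium (0.0389) and p53 targets (0.0259) passed, and without the dimmest 50% of genes p53 targets (0.029) and nerve (-1.01, 0.029). Several lists passed without 1 array. Without Ca/Ca sarcoma 5 these were lymphocytes (0.92, adjusted p = 0.000604), macrophages (0.27, 0.00402), oxidative phosphorylation, erythroid and bone genes (each 0.033) and acute stress (0.0273), and without Ca/Ca sarcoma 3 oxidative phosphorylation (0.041) and acute stress (0.0291). Acute stress passed also without Ca/Ca sarcoma 2 (0.0293). Without Ca/Ca sarcoma 1 these were antigen presentation (-0.88, 0.000547), collagens (0.00112), hypoxia (0.00863) and bone (0.0399). Without Ca/+ sarcoma 1 they were antigen presentation (-1.29, 0.00125), oxidative phosphorylation (0.0195), and collagens and bone (both 0.0466), and without Ca/+ sarcoma 2 endothelium (0.59, 3.47e-05), lymphocytes (1.06, 0.0342), and macrophages and acute stress (both 0.0426).

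The change from muscle to sarcoma was then compared between the genotypes, as the sarcoma minus muscle difference of Ca/Ca minus that of Ca/+. The gene that passed was Eif2s3y, a gene of the Y chromosome, at 5.52 (SE 0.27, adjusted p = 0.00687). It stood at 7.65 in the Ca/+ muscle and from 2.05 to 2.32, at the floor, on the other 7 arrays. The difference thus came from that 1 muscle, and 5.52 is a lower bound. The sarcoma means were 2.18 in Ca/Ca and 2.07 in Ca/+. Xist, the RNA of the inactive X chromosome, chosen after its values were seen, stood at 5.59 in the Ca/+ muscle and from 9.34 to 10.90 on the others. The call of Eif2s3y was lost without Ca/Ca sarcoma 2 (adjusted p = 0.0634), Ca/+ sarcoma 1 (0.115) or Ca/+ sarcoma 2 (0.11). A total of 895 genes had an unadjusted p under 0.05, where chance gives 620, and each muscle level was 1 array. Over the alternatives the count ran from 0 to 17 and the adjusted p of Eif2s3y from 0.00116 to 0.115.

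The list values below rest on 1 muscle per genotype, so they hold the difference of those 2 samples and the spread between muscles was not measured. Their p-values compare the genes of a list with other genes and do not show that the genotypes differ. Between the 2 muscles the medians (Ca/Ca minus Ca/+) were 0.78 for cell cycle, 1.33 for macrophages and -2.06 for adipocytes, against -0.84, -0.12 and 0.12 between the sarcomas. The median of the sarcoma minus muscle difference, Ca/Ca minus Ca/+, was negative for cell cycle genes (-1.91, camera adjusted p = 6.5e-21), collagens (-1.39, 3.48e-09), macrophages (-1.54, 2.02e-06), nerve genes (-1.04, 4.23e-05), fibroblasts (-0.84, 0.000277), ribosome biogenesis (-0.41, 0.00056), proteases (-0.90, 0.00195), protein folding (-0.42, 0.00234), imprinted genes (-1.37, 0.00721), MAPK output (-0.70, 0.00779) and antigen presentation (-1.32, 0.0223). The medians were positive for adipocytes (1.93, 1.19e-07), fatty acid use (0.71, 2.02e-06), acute stress (0.65, 0.00779), ribosomal protein genes (0.18, 0.0183), contractile genes (0.52, 0.0216) and endothelium (0.44, 0.0257). With an estimated correlation no call held, with adjusted p from 0.292 for nerve and 0.325 for cell cycle to 0.711 for contractile genes and 0.74 for antigen presentation, and the directional test of fry passed for nerve genes alone (0.000792). Adjusted over the list alone, 10 cell cycle, 4 nerve (Nefl, Nefm, Pmp22 and Ncmap), 2 fibroblast (Cd44 and Snai2), 2 MAPK output (Ccnd1 and Fosl1), 1 collagen list (Tnc), 1 protease list (Timp1) and 1 imprinted list gene (Hmga2) were lower. In the same way 5 adipocyte (Cidea, Lep, Lipe, Pparg and Retn), 1 fatty acid (Ppara) and 1 ribosomal protein gene (Rpl27a) were higher, and the other called lists had 0. Pmp22, Ncmap, Snai2, Lep, Lipe, Pparg and Retn were named after their values were seen.

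Named members had these values, none past the threshold. They were Ccnd1 (-3.34) and Birc5 (-2.99) for cell cycle, Tnc (-6.06) and Postn (-3.42) for matrix, Arg1 (-4.47) and Fcgr1 (-3.29) for macrophages, Nefl (-7.49) and Nefm (-5.59) for nerve, and Cd44 (-2.66) and Tagln (-2.91) for fibroblasts. They were Nop2 (-0.79) and Utp20 (-0.77) for ribosome biogenesis, Timp1 (-4.04) and Mmp3 (-2.52) for proteases, Pdia3 (-1.10) and Kdelr3 (-0.84) for folding, Hmga2 (-4.44) and Dlk1 (-3.65) for imprinted and growth genes, Fosl1 (-2.44) for MAPK output with Ccnd1, and Ifit1 (-4.06) and Oasl2 (-3.98) for interferon response. The Ca/+ muscle levels of Arg1, Nefl and Nefm lay at the floor, so the values of these 3 are bounds. Positive values were those of Cidea (4.44) and Ucp1 (3.40) for adipocytes, Ppara (2.75) and Cd36 (1.66) for fatty acid use, Fosb (2.65) and Fos (1.67) for stress, Rpl27a (2.15) and Rps6 (0.74, with the other probe set of opposite sign) for ribosomal proteins, Tnnc1 (2.36) and Tnnt1 (2.35) for contraction, and Ramp2 (1.56) and Tek (1.17) for endothelium. Ppara lay at the floor in both sarcoma groups and in the Ca/Ca muscle, so its value reflects the Ca/+ muscle (5.95) alone. Over the alternatives Kdelr3 ran from -1.48 to -0.194, Tek from 0.515 to 1.82 and Rps6 from 0.244 to 1.09.

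Calls of lists were lost without 1 array for antigen presentation (Ca/Ca sarcoma 5, -0.52, adjusted p = 0.165, or Ca/+ sarcoma 2, -0.51, 0.453), for contractile genes (Ca/Ca sarcoma 2, 0.40, 0.0824), and without Ca/+ sarcoma 1 for endothelium (0.067, 0.585), MAPK output (-0.26, 0.0794) and ribosomal protein genes (0.14, 0.0794). Without Ca/+ sarcoma 1 the contractile median turned to -0.35 (adjusted p = 0.552) and that of antigen presentation moved to -2.39, and without Ca/+ sarcoma 2 those of contractile genes and endothelium moved to 1.51 and 0.838. Of 17 alternatives of any kind, 11 kept the call of antigen presentation, 14 of contractile genes, 15 each of endothelium and ribosomal protein genes, and 16 each of acute stress, imprinted genes and MAPK output. Of lists without a call, cytokines stayed without one in 7 of the 17, the kinases in 9 and the Cdkn2 and Rb axis in 11. The median took the other sign in at least 1 alternative for 13 of 15 lists without a call and for 1 of 17 with a call. The lists that did not pass had medians and adjusted p of 0.26 and 0.0844 for myogenic regulators, 0.11 and 0.551 for oxidative phosphorylation, -0.15 and 0.617 for glycolysis, -0.20 and 0.817 for neutrophils (the test pointed up), 0.52 and 0.314 for lymphocytes, -0.26 and 0.059 for cytokines, 0.47 and 0.533 for erythroid genes, and -0.085 and 0.511 for skin. They were -0.0076 and 0.314 for bone and cartilage, 0.0034 and 0.467 for p53 targets, -0.33 and 0.0557 for the Cdkn2 and Rb axis, 0.042 and 0.873 for microRNA processing, -0.24 and 0.369 for hypoxia, -0.19 and 0.301 for housekeeping genes and -0.15 and 0.0514 for receptor tyrosine kinases. Without 1 array some of these passed: lymphocytes without Ca/Ca sarcoma 5 (1.12, adjusted p = 0.00677), the kinases without Ca/Ca sarcoma 5 (0.0425), Ca/Ca sarcoma 1 (0.0263) or Ca/+ sarcoma 2 (0.03), cytokines without Ca/Ca sarcoma 3 (0.0382), Ca/Ca sarcoma 1 (0.0152) or Ca/+ sarcoma 1 (0.00543), hypoxia without Ca/Ca sarcoma 1 (0.0441) and the Cdkn2 and Rb axis without Ca/+ sarcoma 2 (0.0127).

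The 2 muscles had 1 array each, so their differences are values with no test. The Ca/Ca muscle held more RNA of macrophage and nerve genes, and the Ca/+ muscle more of adipocyte genes. Rnase2a, a ribonuclease gene, stood at 12.09 in the Ca/Ca and 3.68 in the Ca/+ muscle, Arg1, the arginase gene, at 9.58 and 2.28, and Nefl at 9.05 and 3.13. In the other direction Ucp1, an uncoupling protein, stood at 4.58 and 10.48, Eif2s3y at 2.25 and 7.65, and Glycam1 at 3.62 and 8.42. A total of 557 genes were over 2-fold higher in the Ca/Ca muscle and 313 in the Ca/+ muscle. All 28 macrophage genes (median 1.33) and all 26 antigen presentation genes (median 0.94) were higher in the Ca/Ca muscle, as were 24 of 27 collagen genes (1.15) 12 of 13 nerve genes (1.03) and 37 of 41 cell cycle genes (0.78), while 0 of 14 adipocyte genes were (-2.06).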

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

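Tests chosen only after the result was seen were those of regenerating fibres, of fewer cells of every type in Ca/Ca sarcoma 5, of the choice of genes by the Ca/+ muscle and of the chromosome stretch that ends at Tfdp1. The number of genes called between sarcoma and muscle was 3256 for the real grouping and at most 1 for the other 27 of the 28 splits of the 8 arrays into 6 and 2. Chance is argued against, as 1 split of 28, the real grouping itself, gave as many. It is not excluded, since 28 splits allow no permutation p below 0.0357. Every other split put at least 1 muscle with sarcomas, which widens the spread within a group.

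Genes high in sarcomas were also high in the Ca/Ca muscle, where 100% of 34 genes at least 8-fold above the Ca/+ muscle in each sarcoma stood above the Ca/+ muscle (median 3.02). A choice by a low level in the Ca/+ muscle favours this, but is argued against as the whole source by the same choice made with the Ca/Ca muscle, which gave 0 genes, a test and bound settled only after an earlier one with 5 genes (5 of 5 higher) had left the question open, while 187 genes at least 8-fold below the Ca/+ muscle in each sarcoma differed by -0.247 (62% lower). A scaling difference between the arrays is argued against, since the lowest median over the scalings was 2.80, and so are regenerating fibres, whose 8 embryonic fibre genes had a median difference of 0.129. RNA of sarcoma tissue in the Ca/Ca muscle sample is a candidate explanation for these 34 genes, since the bounds set for it before the values were seen were met (100%, quartiles 1.9-fold apart), although its reading was changed to open and back after they were seen. The muscles were said to come from hind limbs without a tumour. Some other large differences between the muscles argue against it as their source, as the Ca/Ca muscle lay above every sarcoma. Rnase2a stood at 12.09 there and at most 8.35 in a sarcoma, Wfdc18 at 9.61 and 5.22, and Mucl1 at 9.33 and 6.69. Arg1 and Nefl did not lie above every sarcoma. The shares of sarcoma RNA that the genes imply (19.5% in the middle, 15.9% and 30.2% at the quartiles) ran from 3.28% for Klhdc8a and 5.59% for Ptgs2 to 61.3% for Cdh11, 107% for Xist and 112% for Arg1, where 1 admixed share would give similar values. The Ca/+ muscle alone held Y chromosome RNA (Eif2s3y at 7.65) and had the lowest Xist (5.59). The 2 muscles thus differed in sex markers, and the share of Xist does not measure sarcoma RNA. Whether sex or an inflamed muscle accounts for other genes stays open and untested.

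Tfdp1 and genes before it in the chromosome order were higher in Ca/+ sarcomas, most of all in Ca/+ sarcoma 1, where all 17 genes measured from Naxd to Tfdp1 had a median of 2.38 above the Ca/Ca sarcomas (0.42 in Ca/+ sarcoma 2) and 15 of them, a list made without 1700016D06Rik and Sox1, 2.41 (0.54). From Pcid2 to Tfdp1 each measured gene of Ca/+ sarcoma 2 also stood above all 4 Ca/Ca sarcomas. Tfdp1 stood there at 10.48 against 8.31 to 8.49, Pcid2 at 8.35 against 6.23 to 6.67 and Tmco3 at 7.34 against 5.94 to 6.25. A probe artifact is argued against by the other Pcid2 probe set, which differed by 2.61, and a gain on both sides of Tfdp1 by the median of its 10 neighbours, 0.167, with 1.58 before Tfdp1 and -0.16 after it, although 0.167 still lay at percentile 97.3 of 10000 random gene sets. In a scan of runs of 9 neighbouring genes over 12367 genes, the highest run of Ca/+ sarcoma 1 lay at 2.38 above the mean of the 4 Ca/Ca sarcomas and the muscles, between Irs2 and Arhgef7, and held 4 of the 15 listed genes, while the highest of 1000 shuffled orders reached 1.43. How many of the 15 listed genes the run had to hold was settled only after the scan was seen. This run was the first of several overlapping runs with the same median, and later ones, up to Naxd to F7, held more listed genes. A stricter requirement of 5 would have left the question open for this run but not for those. All of these runs ended before Tfdp1. A gain of a stretch that ends at Tfdp1 in Ca/+ sarcoma 1 is a candidate explanation, but DNA copy number was not measured and the genotype of this tumour stays an untested alternative.

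Ca/Ca sarcoma 5 held far less RNA of immune cell and interferon genes than the 5 other sarcomas, by a list mean of -3.02 for antigen presentation, -1.90 for lymphocytes and -1.27 for macrophages, though the macrophage list genes Cd14 (10.14 against 9.32) and Cd68 (9.24 against 9.23), chosen after their values were seen, were not lower. Degraded RNA is argued against by its 3' minus 5' control difference of 0.341, inside the range of the other sarcomas (0.236 to 0.418), and scaling by the median of 75 immune genes, which stayed at -1.83 or lower under every scaling. Fewer cells of every non-tumour type cannot be told apart from fewer immune cells alone, since the endothelial list mean differed by -0.0621 and the adipocyte list mean by -1.10. The cell cycle (-1.19) and imprinted (-0.817) list means were also the lowest of the 6 and the skin list mean the highest (0.974), so the array stood apart in more than immune genes, its source stays open, and neither cell counts nor histology were analysed here.

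Chance marks about 1 in 20 groups as having a sample far from the others, and 26 of 340 tested groups were marked. Among the 4 Ca/Ca sarcomas, sarcoma 5 stood apart in 8 of them, at list means of 8.54 for macrophages, 4.57 for lymphocytes and 6.85 for endothelium and at levels of 6.61 for Birc5, 8.60 for Ms4a7, 8.10 for Il1rap, 3.39 for Fas and 5.40 for Ndn. In the same group sarcoma 1 stood apart at 6.02 for Myf6, 5.21 for Bbc3 and 8.48 for Tnni2. Sarcoma 3 stood apart there at 8.14 for Fosl1, 5.76 for Zmat3 and 3.68 for Tnfrsf10b. Among all 6 sarcomas, Ca/Ca sarcoma 5 stood apart at 5.46 for Rpl14, 11.05 for Sec61a1, 8.78 for Etv4 and 5.40 for Ndn. Ca/Ca sarcoma 1 did so at 8.32 for the acute stress list mean and 8.71 for Phlda3, and Ca/Ca sarcoma 3 at 7.06 for Myc. Ca/+ sarcoma 1 did so at 2.87 for Ddit4l and 4.57 for Tnfrsf10b, and Ca/+ sarcoma 2 at 4.35 for Ckmt2, 7.48 for Aen and 8.78 for Cdkn2a.

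The value of 5.52 for the Y chromosome gene Eif2s3y in the comparison of changes came from the Ca/+ muscle alone, which held Y RNA (7.65 against 2.25 in the Ca/Ca muscle), while the sarcoma means were 2.18 and 2.07. List medians of this difference, which rest on 1 muscle per genotype and do not show that the genotypes differ, were positive for contractile genes (0.523), fatty acid use (0.707), endothelium (0.445), adipocytes (1.93), ribosomal protein genes (0.179) and acute stress (0.653). They were negative for cell cycle (-1.91), collagens (-1.39), proteases (-0.899), fibroblasts (-0.837), macrophages (-1.54), antigen presentation (-1.32), nerve (-1.04), MAPK output (-0.704), ribosome biogenesis (-0.41), protein folding (-0.423) and imprinted genes (-1.37). Of 2246 probe sets without 1 named gene, 345 changed between sarcoma and muscle (198 higher, 147 lower), which is 15.4% against 26.3% of named genes.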

How the results depend on the processing

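The tests in this part were planned, except the fits without both the Ca/Ca muscle and Ca/Ca sarcoma 5 and without the genes of the Tfdp1 stretch, which were chosen only after the results were seen. For sarcoma against muscle the count of 3256 genes moved to 1799 (754 higher, 1045 lower) at 2-fold, 871 (216 and 655) with treat, 5260 (2770 and 2490) over every probe set, 601 (91 and 510) with Ca/Ca arrays only and 1287 (592 and 695) with Ca/+ arrays only. The split moved to 1056 higher under cyclic loess, 714 higher and 3062 lower under housekeeping centring, 574 and 3691 under ribosomal protein centring, 820 lower under hybridization control centring and 884 lower without the dimmest 50% of genes. Leaving out 1 array gave 1195 to 3451 genes (372 to 1772 higher, 823 to 1679 lower), the lowest without the Ca/+ muscle, and 1040 higher without the Ca/Ca muscle. Trend and robust eBayes gave 3168 genes, array weights 3727, the mean of probe sets 3247 and genotype as a covariate 3170. For Ca/Ca against Ca/+ sarcoma the count of 0 moved to 1 lower gene under hybridization control centring and without Ca/+ sarcoma 1 (range 0 to 1), and stayed at 0 without the Tfdp1 stretch (961 at an unadjusted p under 0.05). For the interaction the count of 1 moved to 17 (11 higher, 6 lower) with trend and robust eBayes, 13 (8 and 5) with array weights, 6 (5 lower) under hybridization control centring, and 0 without the dimmest 25% or 50% of genes and under ribosomal protein centring, and leaving out 1 array gave 0 to 1, with 0 without Ca/Ca sarcoma 2, Ca/+ sarcoma 1 or Ca/+ sarcoma 2. For each moved count the cause was not tested, except that a minimum fold change and a larger set of probe sets change the count by construction, and so does leaving out dim genes for the interaction, as Eif2s3y is then not tested. Between the genotypes the nerve list turned to -1.01 (adjusted p = 0.029) without the dimmest 50% of genes, and the contractile list turned to -0.31 (0.0604) between the genotypes and to -0.346 (0.552) in the interaction without Ca/+ sarcoma 1 (against 1.09 and 1.51 without Ca/+ sarcoma 2), and the cause was not tested. Tumour numbers as a block, which compares only sarcomas 1 and 2 of each genotype, gave 0 genes (857 at an unadjusted p under 0.05). The antigen presentation list turned to 0.481 (adjusted p = 0.0052), and its sign also turned without Ca/Ca sarcoma 5. Other causes were not tested. Arrays of the same number shared only that number, with r across genes of -0.189 and 0.293. Not possible were the interaction without either muscle, a replicate block for tissue, since muscles carry no number, and a pseudocount, since the table is log2.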

Other observations

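The genes of these paragraphs, and the scan of neighbouring genes, were chosen only after the values were seen, and none of the differences was tested unless said. In Ca/Ca sarcoma 1 a run of neighbouring genes on 1 chromosome, from Casp4 to Mmp1a, stood at a median of 3.27 above the 5 other sarcomas, where the highest of 1000 shuffled gene orders reached 1.24. The growth factor gene Pdgfd was at least 6.34 higher there, as the others lay at the floor, Dcun1d5 3.32 and the protease gene Mmp13 3.43, and beyond the run the transcription coactivator gene Yap1 was 3.72 higher and the survival genes Birc2 and Birc3 3.79 and 3.49, with Tmem123 at 2.83. Several genes of this region were also high in Ca/Ca sarcoma 3 against the 4 others, with Mmp10 3.79 higher (11.79, above the 10.94 of Ca/Ca sarcoma 1), Mmp13 2.73, Mmp1b at least 2.62, Mmp12 2.52, Mmp1a 2.39, Dcun1d5 2.01 and Birc3 1.71, while Pdgfd lay at the floor and Yap1 was 0.83 higher there. Immunoglobulin kappa genes formed the highest run of Ca/Ca sarcoma 3 (2.06, highest shuffle 1.12), immunoglobulin heavy chain genes lay in that of Ca/Ca sarcoma 2 (1.24, highest shuffle 1.09), and class II genes of antigen presentation in that of Ca/+ sarcoma 2 (1.09, highest shuffle 1.05). Ca/+ sarcoma 1 had the run from Irs2 to Arhgef7 (2.30, highest shuffle 0.976), while in Ca/Ca sarcoma 5 the highest run (1.03) was reached by 68 of 1000 shuffled orders.

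Ca/Ca sarcoma 5 also held RNA that was low in the 5 other sarcomas, such as the aldehyde dehydrogenase gene Aldh3a1 (8.04 against a mean of 2.12), the chloride channel gene Cftr (9.29 against 4.09), the neuropeptide genes Calcb (11.59 against 6.70) and Tac1 (11.61 against 6.88), and the stem cell factor gene Sox2 (9.26 against 5.36). Its chemokine gene Cxcl9 stood at 2.33 against 9.03, while the macrophage genes Cd163 (8.83 against 7.42) and Arg1 (10.57 against 8.19) were higher than the mean of the others. Between the muscles, single genes higher in the Ca/Ca muscle were Wfdc18 (9.61 against 4.64), Mucl1 (9.33 against 5.13), Csn3 (8.04 against 3.69), Ear3 (6.75 against 3.41) and Siglecf (5.56 against 2.29). Each of these also stood higher in the Ca/Ca muscle than in every sarcoma. Single genes higher in the Ca/+ muscle were Csrp3 (7.15 against 11.61), Ankrd2 (7.21 against 9.92), Ms4a1 (6.13 against 9.07) and Myh7 (6.51 against 8.28), while 26 of 37 contractile genes were higher in the Ca/Ca muscle (median 0.092). The Y chromosome gene Kdm5d stood at 4.61 in the Ca/+ muscle and at most 2.28 on the 7 other arrays.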
